A study of Homo sapiens with 16 samples.

How the data were processed

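The samples were 16 ependymomas, tumours of the lining of the brain's ventricles and the spinal canal, profiled by enhanced reduced representation bisulfite sequencing (ERRBS). In this assay DNA is digested with MspI, fragments of 84 to 334 bp are kept and treated with bisulfite, and unmethylated cytosines are read as T while methylated ones are read as C. Size selection enriches for DNA rich in CpG, so the values describe that part of the genome. The labels placed 12 tumours in the posterior fossa (PF), called negative in 8 and positive in 4, and 4 in the supratentorial compartment (ST). They do not say which marker negative and positive refer to. The labels' protocol text speaks of cell lines, whereas the source names say ependymoma, so the samples were treated as primary human tumours. Nothing in the labels says that each sample came from a separate patient, so p-values measure the spread between these samples, which may be partly technical.

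The submitters' processing notes name CASAVA 1.8.2, Bismark 0.5.4 and Bowtie 0.12.7 and the builds hg18 and hg19, with no order or role. Positions on chromosomes 4 and 19 run past the ends of these chromosomes in hg19, so coordinates here are those of hg18. The deposited tables hold 1 cytosine of a CpG per line with its strand, the coverage (a count of reads) and the percent of reads with C and with T, per the file headers. The lowest coverage deposited by the authors was 10 reads. Multiplying the deposited percent by the deposited coverage gave whole reads within 0.01 reads for 100% of values, so methylated and unmethylated read counts were recovered from these columns. Bases other than C and T made up 0.0182% to 0.0234% of reads per tumour. How the authors trimmed reads, treated duplicates and estimated conversion is not given in the sources used here.

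Autosomal cytosines were used, and the sex chromosomes were not analysed here. Each tumour had 2628004 to 2886434 covered cytosines, a total coverage summed over cytosines of 105950617 to 155634766 and a median coverage of 33 to 48 reads. Of 3496003 cytosines listed in at least 1 tumour, 60.5% had at least 10 reads in all 16. Another 13366 were left out because their coverage lay above an upper percentile of a tumour's coverage, where collapsed repeats can gather reads, which left 2100186 shared cytosines. Windows of 1 kb with at least 3 shared cytosines were tested, 142454 in number, with a median of 6 cytosines and 308 reads per window and tumour, and 83 reads at the lowest 5%. Reads carry no molecular identifiers, so the depth speaks for counting error only. CpG surroundings were the number of other covered CpGs within 250 bp, called CpG-sparse below 10, CpG-intermediate from 10 to 29 and CpG-dense from 30. They come from covered CpGs, not from the genome sequence, and a window took the mean over its cytosines.

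For each tumour 7 measures were computed. They were the mean methylation of shared cytosines, the mean within each of the 3 surroundings, and the shares of cytosines at 20% or less, between 20% and 80% and at 80% or more. The 3 comparisons of groups were tested with exact two-sided permutation tests on the difference of means, with Benjamini-Hochberg adjustment over the 21 tests. With 4 tumours against 4 the smallest exact p is 0.0286, and with 8 against 4 it is 0.00202. Windows were tested with a quasi-binomial logistic model of methylated and unmethylated reads over the tumours of the 2 groups compared, with an F test, a Pearson dispersion of at least 1 and Benjamini-Hochberg adjustment over the windows. A window was called at an adjusted p under 0.05 and a difference of at least 20 percentage points. The distance between a pair of tumours was the mean absolute difference of methylation over windows, and between-group minus within-group distance was tested with a one-sided exact permutation test.

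The windows named by coordinates were the 6 with the largest difference in each direction of each comparison among those called. These rules, the groups, the tests and most alternatives were set before the data were examined. The alternatives were a coverage minimum of 20 reads, no upper limit on coverage, each tumour's own cytosines, weighting by reads, windows of 500 bp and each cytosine on its own. Further ones were thresholds of 10 and 30 points, all 3 groups in 1 fit and a correlation distance. The rest were limma on logit methylation with an offset of 0.5 reads, limma on values centred per tumour, the replicate number as a block, and each tumour left out in turn. Thinning of every cytosine to 10 reads, limma without the block on the same-numbered tumours and fits with 4 of the 8 PF negative tumours were added after seeing the data.

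Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The window test was tested on simulated data drawn from the real depths and spreads, with 100 windows lowered by 20 points and 100 by 40 points. For PF negative against PF positive it called 4 of the 100 windows lowered by 20 points, 30 of the 100 lowered by 40 points and 1 of 142254 unchanged windows. For PF negative against ST the numbers were 2, 39 and 3, and for PF positive against ST they were 3, 9 and 5. Few windows were changed in the simulation, so its adjustment was stricter than that of the real data, and a fall of exactly 20 points lies at the threshold. These rates do not carry over to the real comparisons. The closest pair of tumours, PF negative 3 and PF negative 5, lay 5.52 points apart against 1.86 from counting error alone. No pair of tables was thus the same library within counting error, which does not show that the samples are independent.

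The annotation supplied was of another build than the coordinates and coordinates were not converted, so genes, promoters and the gene lists drawn up for promoters were not analysed here and regions are given by position.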

Results

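DNA methylation at CpG cytosines was compared between 8 PF negative, 4 PF positive and 4 ST ependymomas, which addresses how the 3 tumour classes differ from one another. Per tumour, 2628004 to 2886434 autosomal cytosines were covered at 10 reads or more. Their coverage summed to 105950617 to 155634766, with a median of 33 to 48 reads per cytosine. Values are over the 2100186 cytosines covered in all 16 tumours, or over the 142454 windows of 1 kb they fill, with a median of 308 reads per window and tumour. Mean methylation was 32.7% ± 1.72 (SD, n = 8) in PF negative, 34.97% ± 0.864 (SD, n = 4) in PF positive and 37.4% ± 2.37 (SD, n = 4) in ST tumours.

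**Figure D1:**
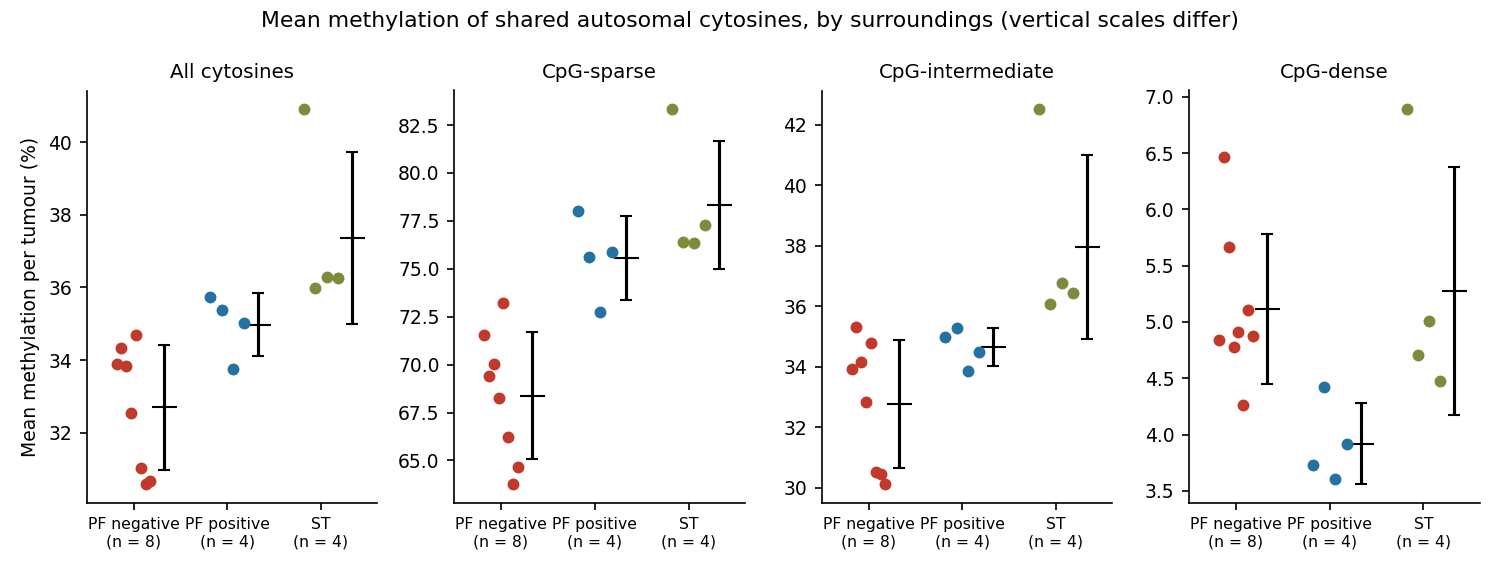
Methylation (percent) per tumour in the 3 groups, by CpG surroundings, with points for tumours and bars for the group mean and SD, on vertical scales that differ between panels. At CpG-sparse cytosines the PF negative mean was 68.4% against 75.6% in PF positive and 78.3% in ST tumours, and at CpG-dense cytosines the means were 5.11%, 3.92% and 5.27%.

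The first comparison set PF negative against PF positive tumours, both from the posterior fossa. Averaged over cytosines, PF negative tumours were less methylated where CpGs are sparse and more methylated where they are dense. At CpG-sparse cytosines methylation was 68.4% ± 3.31 (SD, n = 8) against 75.6% ± 2.18 (SD, n = 4). The difference was −7.18 points (SE 1.60), with 7 of 8 PF negative tumours below the lowest PF positive tumour (exact permutation p = 0.00606, adjusted p = 0.0212). At CpG-dense cytosines it was 5.11% ± 0.669 (SD, n = 8) against 3.92% ± 0.359 (SD, n = 4). This was a difference of 1.19 points (SE 0.297), with 7 of 8 above the highest PF positive tumour (exact permutation p = 0.0101, adjusted p = 0.0236). The difference was not general to CpG-dense DNA. In the 12834 of 14529 CpG-dense windows that stood under 10% in ST tumours the difference was 0.222 points (SE 0.101) and did not pass its test. At CpG-intermediate cytosines the difference of −1.89 points (SE 0.809) did not pass the test (exact permutation p = 0.113, adjusted p = 0.148). With cytosines weighted by reads it did pass, at −2.08 points (SE 0.644, adjusted p = 0.0386), and the CpG-dense difference was smaller, at 0.671 points (SE 0.183, adjusted p = 0.0339).

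PF negative tumours also held more cytosines at in-between levels. The share between 20% and 80% was 14.1% ± 2.19 (SD, n = 8) against 9.61% ± 1.94 (SD, n = 4). It was higher by 4.53 points (SE 1.24, exact permutation p = 0.0101, adjusted p = 0.0236), with 6 of 8 tumours above the PF positive range. The share at 80% or more was 26.1% ± 2.79 (SD, n = 8) against 30.7% ± 1.75 (SD, n = 4). It differed by −4.62 points (SE 1.32, exact permutation p = 0.0141, adjusted p = 0.0297), with 6 of 8 below it. The share at 20% or less differed by 0.0859 points (SE 0.487, adjusted p = 0.938 from the exact permutation test). The overall mean differed by −2.28 points (SE 0.747, exact permutation p = 0.0343, adjusted p = 0.0481), with 4 of 8 PF negative tumours below the PF positive range. This last call was lost without PF negative 4, 6, 7 or 8 or without any 1 PF positive tumour (differences of −2.68 to −1.98 points), and with a coverage minimum of 20 reads (−1.82 points, adjusted p = 0.0764). The CpG-sparse call ended without PF positive 1 or 4 (−6.36 and −7.07 points, both at adjusted p = 0.0545) and the CpG-dense call without PF positive 1, 3 or 4 (1.13, 1.09 and 1.19 points). The calls of both shares ended without PF positive 1, 2 or 4, at 3.89, 4.38 and 4.44 points between 20% and 80% and −4.08, −4.38 and −4.58 points at 80% or more.

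Among single windows that differed by 20 points or more, most CpG-sparse ones were lower and most CpG-dense ones higher in PF negative tumours. Of 142454 windows, 3748 were called between PF negative and PF positive tumours, 3234 of them lower and 514 higher in PF negative tumours. Of the lower windows 2676 were CpG-sparse, 555 CpG-intermediate and 3 CpG-dense, whereas of the higher windows 100 were CpG-sparse, 285 CpG-intermediate and 129 CpG-dense. For CpG-dense windows this rested on the threshold of 20 points, since at an adjusted p under 0.05 alone 190 were higher and 170 lower, and at an unadjusted p under 0.05 801 were higher and 1330 lower. The windows called lower averaged 40.5% in PF negative and 76.3% in PF positive tumours, and stood at 71.8% in ST tumours, which had no part in this test. The windows called higher averaged 67.3% against 27.8%, with ST tumours at 50.0%, and their CpG-dense members averaged 66.4% against 24.8%, with ST at 44.5%.

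The count of 3748 was 691 without PF positive 1, 1211 without PF positive 4 and 5822 without PF positive 2. It was 2275, 1904, 1971 and 2008 without PF negative 3, 6, 7 and 8. The 514 higher windows were 98, 1109, 331 and 155 without PF positive 1, 2, 3 and 4, and 328, 275, 312, 267 and 284 without PF negative 2, 3, 6, 7 and 8. The split changed once values were centred per tumour. On logit values as they stood, limma called 1025 windows higher and 6965 lower in PF negative tumours. On logit values centred per tumour it called 1782 higher and 1672 lower. Most tested windows were CpG-sparse (92662), so centring can also remove part of a fall shared by them.

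**Figure D2:**
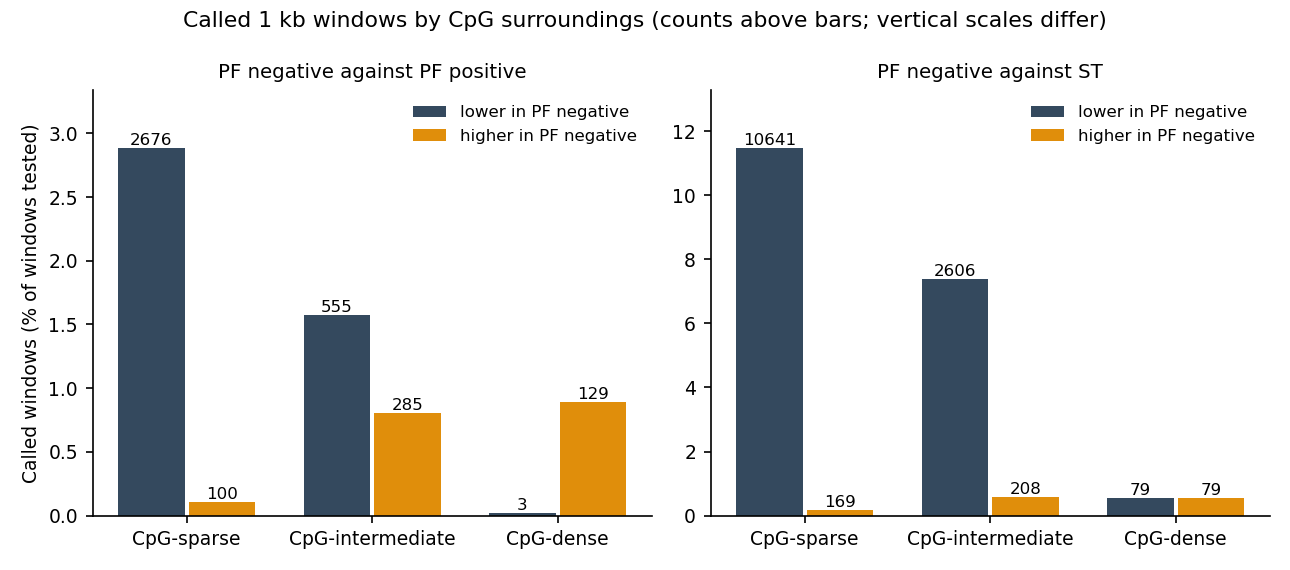
Windows of 1 kb called lower and higher in PF negative tumours against PF positive (left) and ST (right) tumours, as a percent of windows tested in each CpG surrounding, with the counts above the bars. Between PF negative and PF positive tumours 2676 CpG-sparse windows were lower and 100 higher, while 3 CpG-dense windows were lower and 129 higher.

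Among windows higher in PF negative tumours, that on chromosome 4 from 48188001 to 48189000 had the largest difference. It was CpG-dense, with 7 cytosines and 255 to 705 reads per tumour, and stood at 77.1% ± 11.3 (SD, n = 8) against 8.65% ± 5.59 (SD, n = 4). The difference was 68.5 points (SE 4.88, adjusted p = 0.00277), and ST tumours stood at 65.6% ± 10.6 (SD, n = 4). The window on chromosome 2 from 136593001 to 136594000, which was CpG-intermediate, stood at 71.6% ± 20.2 (SD, n = 8) in PF negative and 4.04% ± 1.34 (SD, n = 4) in PF positive tumours (adjusted p = 0.0094). It was also the window with the largest rise against ST tumours, where 0 of 1346 reads, summed over cytosines and the 4 tumours, were methylated. This allows a share of up to 0.223% in these reads if they were independent of one another, which was not shown. The window held 6 cytosines with 76 to 535 reads per tumour. The window on chromosome 3 from 198178001 to 198179000 stood at 87.4% ± 3.83 (SD, n = 8) against 19.6% ± 30.6 (SD, n = 4). Its PF positive spread exceeded their mean, and its call was lost without PF positive 1 or 4.

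Among windows lower in PF negative tumours, those with the largest differences went from nearly full to nearly no methylation. The window on chromosome 18 from 46326001 to 46327000 was at 10.7% ± 7.96 (SD, n = 8) in PF negative and 92.1% ± 6.05 (SD, n = 4) in PF positive tumours. The difference was −81.5 points (SE 4.13, adjusted p = 0.00185). On chromosome 9 the window from 26416001 to 26417000 was at 9.88% ± 7.22 (SD, n = 8) against 90.5% ± 3.65 (SD, n = 4). On chromosome 1 that from 195375001 to 195376000 was at 16.1% ± 11.7 (SD, n = 8) against 94.5% ± 2.63 (SD, n = 4). ST tumours stood at 95.5% ± 0.630 (SD, n = 4) in the chromosome 1 window, and varied widely in the other windows of this set, as at chromosome 18 with 58.5% ± 43.2 (SD, n = 4). Each of the 12 windows named between PF negative and PF positive tumours lost its call in at least 1 alternative. All 12 did so with the replicate number as a block, which holds only the same-numbered tumours and called 0 windows in this comparison. That loss thus says nothing about these windows in particular. With a tumour left out 4 of them lost their call.

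**Figure D3:**
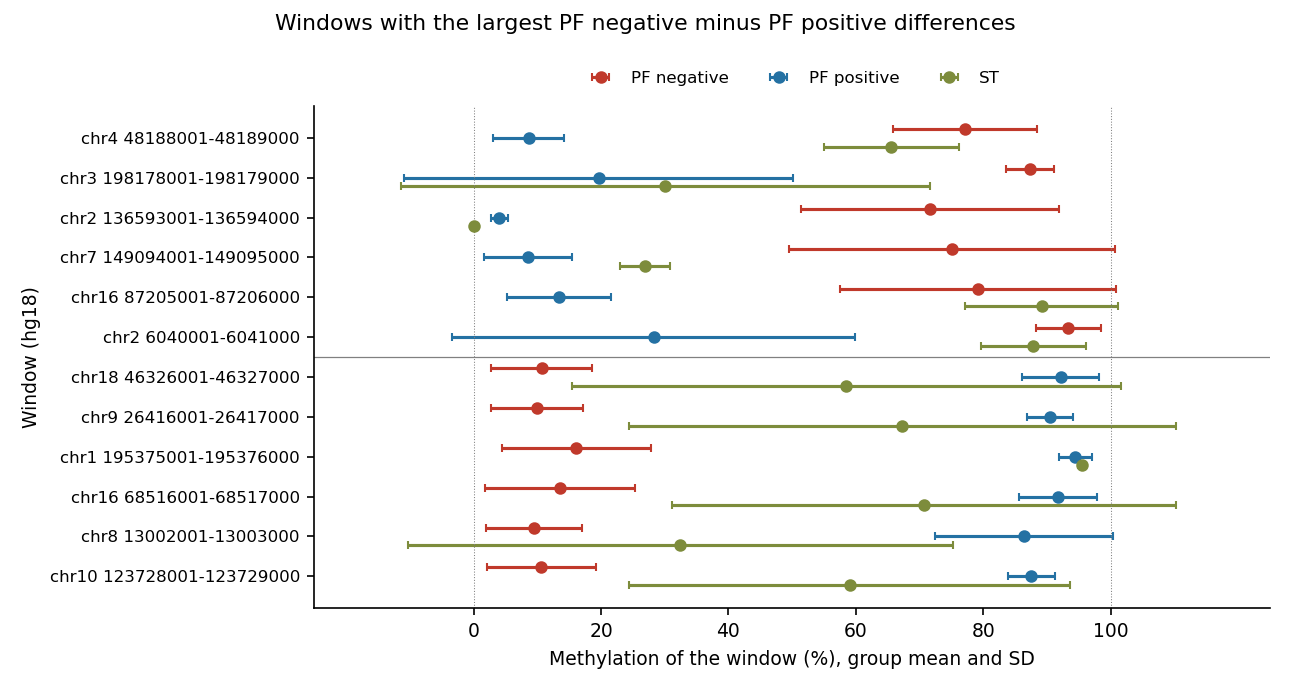
Methylation (percent) of the 6 windows highest (above the line) and the 6 lowest (under it) in PF negative relative to PF positive tumours, with group means and SD bars, which can extend beyond the dotted lines at 0% and 100% because they are symmetric. The window on chromosome 4 from 48188001 has means of 77.1% in PF negative, 8.65% in PF positive and 65.6% in ST tumours.

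The comparison of PF negative with ST tumours asked how these posterior fossa tumours differ from supratentorial ones. PF negative tumours were less methylated at CpG-sparse cytosines, at 68.4% ± 3.31 (SD, n = 8) against 78.3% ± 3.35 (SD, n = 4). The difference was −9.95 points (SE 2.04), with 8 of 8 tumours below the ST range (exact permutation p = 0.00202, the smallest possible, adjusted p = 0.0141). The overall mean differed by −4.66 points (SE 1.33, exact permutation p = 0.00202, adjusted p = 0.0141, 8 of 8 below). The CpG-intermediate mean differed by −5.19 points (SE 1.70, exact permutation p = 0.00404, adjusted p = 0.0212, 8 of 8 below). CpG-dense cytosines did not differ detectably, at 5.11% ± 0.669 (SD, n = 8) and 5.27% ± 1.1 (SD, n = 4). The difference was −0.158 points (SE 0.599, exact permutation p = 0.772), which was 0.381 without ST 1. The share of cytosines at 80% or more differed by −7.14 points (SE 1.83, adjusted p = 0.0141 from the exact permutation test, 8 of 8 below). That between 20% and 80% was higher by 4.52 points (SE 1.01, adjusted p = 0.0212 from the exact permutation test), a call lost without ST 1 (3.95 points). The share at 20% or less was higher by 2.62 points (SE 1.07, adjusted p = 0.0236 from the exact permutation test), also lost without ST 1 (1.67 points) and with each tumour's own cytosines (1.39 points, SE 1.02, adjusted p = 0.227).

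Of the 142454 windows, 13782 were called in this comparison, 13326 of them lower and 456 higher in PF negative tumours. The lower windows comprised 10641 CpG-sparse, 2606 CpG-intermediate and 79 CpG-dense windows and averaged 40.1% in PF negative and 76.7% in ST tumours, with PF positive tumours, outside the test, at 61.8%. The higher windows comprised 169, 208 and 79 of these and averaged 63.0% against 24.6%, with PF positive tumours at 36.3%. The equal counts of CpG-dense windows rested on the threshold of 20 points. At an adjusted p under 0.05 alone in the quasi-binomial model 168 were higher and 980 lower, and at an unadjusted p under 0.05 472 were higher and 2486 lower. The count of 13782 was 7201 without ST 1, and the 456 higher windows were 276 without ST 4. In addition, limma called 626 windows higher and 16502 lower on values as they stood, and 1367 higher and 5186 lower on centred values.

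The windows with the largest falls against ST tumours were nearly unmethylated in PF negative tumours. On chromosome 2 the window from 161056001 to 161057000 was at 6.38% ± 4.16 (SD, n = 8) against 90.6% ± 7.37 (SD, n = 4). This was a difference of −84.3 points (SE 3.97, adjusted p = 7.2e-05), with PF positive tumours spread widely, at 42.2% ± 36.8 (SD, n = 4). On chromosome 3 the window from 148625001 to 148626000 was at 1.1% ± 1.06 (SD, n = 8) against 84.4% ± 9.01 (SD, n = 4), with an adjusted p of 8.92e-06. Of the windows higher in PF negative tumours, that on chromosome 17 from 8160001 to 8161000 was at 81.6% ± 13.7 (SD, n = 8) against 10.3% ± 5.64 (SD, n = 4). Another on chromosome 17, from 43963001 to 43964000, was at 81.2% ± 4.87 (SD, n = 8) against 10.4% ± 11.5 (SD, n = 4). PF positive tumours stood at 18.2% ± 18.5 (SD, n = 4) in the former window and at 45.4% ± 32.4 (SD, n = 4) in the latter. All 12 windows named in this comparison kept their calls in every alternative run.

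Windows at which PF negative tumours differed from both other groups were counted next. In all 2114 windows were lower in PF negative tumours in both comparisons, and 139 were higher in both, which is 65.4% and 27.0% of those called against PF positive tumours. Independent lists of these sizes would share 303 and 1.65 windows. With the labels of the 16 tumours permuted, the highest of 100 draws was 0 lower windows and 1 higher window, with medians of 0 and 0. Relabelled tumours called few windows in either comparison, so these draws say little about how far the lists overlap. Splitting the 8 PF negative tumours, so that each comparison used its own 4, gave a median of 52 lower windows (15 to 279 over 70 splits) against 6.81 from independent lists. For higher windows the median was 3 (0 to 11) against 0.0224. The total of 2253 was 443 without PF positive 1 and 736 without PF positive 4, and 1310, 1451, 1034, 1042 and 1102 without PF negative 3, 4, 6, 7 and 8.

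PF positive and ST tumours, 4 against 4, differed by less than the other pairs of groups over CpG-sparse cytosines and windows, a ranking that was not itself tested. ST tumours were more methylated at CpG-dense cytosines, with PF positive minus ST at −1.35 points (SE 0.579). In this measure 4 of 4 PF positive tumours lay below the ST range (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0429). The same p-values held for the overall mean (−2.39 points, SE 1.26), the CpG-intermediate mean (−3.30 points, SE 1.56) and the share at 20% or less (2.54 points, SE 0.972). CpG-sparse cytosines differed by −2.77 points (SE 2.00), which did not pass the test (exact permutation p = 0.257, adjusted p = 0.300) and was −1.11 points without ST 1 and −1.83 without PF positive 3. The share between 20% and 80% differed by −0.0134 points (exact permutation p = 1). Each of the 4 calls was lost without ST 1 (−0.813, −1.20 and −1.78 points for the CpG-dense, overall and CpG-intermediate means, and 1.58 for the share). They were also lost without any 1 PF positive tumour (for the overall mean −2.64, −2.52, −1.98 and −2.40 points without PF positive 1, 2, 3 and 4). In the same order the CpG-dense difference was −1.29, −1.52, −1.25 and −1.35 points, the CpG-intermediate one −3.42, −3.51, −3.04 and −3.25, and that of the share 2.44, 2.62, 2.61 and 2.48. The PF positive tumours that remained still lay outside the ST range, and the differences moved both ways. With so few tumours these losses thus do not show that a difference rested on 1 PF positive tumour. With each tumour's own cytosines none of the 4 passed (−1.39, −3.41 and −3.79 points for the CpG-dense, overall and CpG-intermediate means, and 1.41 for the share, at adjusted p from 0.0545 to 0.267). These means differed by more there than over shared cytosines, so for them the lost calls do not show a smaller difference. Adjusted p also depends on the other tests.

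The test called 20 windows between PF positive and ST tumours, 6 higher and 14 lower in PF positive tumours, while 11163 passed an unadjusted p under 0.05. Those lower included a CpG-dense pair of adjoining windows on chromosome 15, from 72212001 to 72213000 and from 72213001 to 72214000, with 75 and 71 cytosines. They stood at 4.03% ± 2.6 and 4.61% ± 3.16 in PF positive tumours (SD, n = 4) and at 76.7% ± 9.10 and 78.4% ± 9.33 in ST tumours (SD, n = 4). PF negative tumours stood at 5.63% and 3.13% there. Both calls were lost without PF positive 1, 3 or 4 or without ST 2 or 3 in turn. A CpG-dense window on chromosome 7 from 25859001 to 25860000 was at 5.63% ± 2.30 (SD, n = 4) against 73.9% ± 5.55 (SD, n = 4). Its difference was −68.3 points (SE 3.00, adjusted p = 0.00436), and it passed whichever tumour was left out. The window on chromosome 10 from 116297001 to 116298000 was at 86.7% ± 7.56 (SD, n = 4) against 7.40% ± 5.17 (SD, n = 4). Its adjusted p was 0.0443, and the call was lost without PF positive 1, 2, 3 or 4 or ST 1, 2 or 4. The count was 47 without PF positive 2, 38 without ST 3 and 13 without ST 4, and limma called 0 windows with 11356 at an unadjusted p under 0.05. With 1 tumour left out in turn, the 6 higher windows ranged from 1 to 8 and the 14 lower ones from 12 to 43.

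Group sizes differed, so the counts of called windows are not comparable across comparisons as they stand. With 4 of the 8 PF negative tumours, the median over 70 choices was 239.5 windows (60 to 4666) against PF positive and 3617.5 (1360 to 15035) against ST tumours, beside the 20 called between PF positive and ST tumours.

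Over all windows, distances between groups exceeded those within groups on average, while single PF positive tumours were not all nearest their own group. Between PF negative and PF positive tumours the mean distance was 10.7 points against 7.93 within groups, a difference of 2.77 (one-sided exact permutation p = 0.00202). Between PF negative and ST tumours it was 11.7 against 7.77, a difference of 3.93 (one-sided exact permutation p = 0.00202). Between PF positive and ST tumours it was 9.27 against 8.63, a difference of 0.642 (one-sided exact permutation p = 0.0286). This call was lost without PF positive 4 (0.616) or without ST 1, 2, 3 or 4 (0.266, 0.493, 0.727 and 0.476). The nearest group was the tumour's own for all 8 PF negative and all 4 ST tumours, whereas PF positive 1, 2 and 3 lay about as near to ST as to the other PF positive tumours. Their distances to ST were 8.88, 9.07 and 10.28 points, and those to their own group 8.85, 9.12 and 10.23 points.

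The lower methylation of CpG-sparse DNA in PF negative tumours extended over the autosomes. Of 1295 megabases with at least 20 CpG-sparse windows, PF negative tumours had the lower mean in 1277 (98.6%) against PF positive tumours and in 1288 (99.5%) against ST tumours, with median differences of −6.73 and −9.30 points. PF positive tumours had the lower mean in 1165 (89.96%) against ST tumours, with a median of −2.46 points. All 22 chromosomes had a negative difference in each comparison, for PF negative minus PF positive from −5.14 points on chromosome 6 to −9.40 on chromosome 19. Megabases and chromosomes of the same tumours are not replicates, so these counts describe extent and do not test a difference. At CpG-sparse cytosines PF positive minus ST did not pass its test (exact permutation p = 0.257). The largest fall against PF positive tumours lay on chromosome 18 from 74000001 to 75000000 (67.0% against 83.2%), and on chromosome 1 from 147000001 to 148000000 PF negative tumours were higher by 13.6 points (57.7% against 44.1%).

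**Figure D4:**
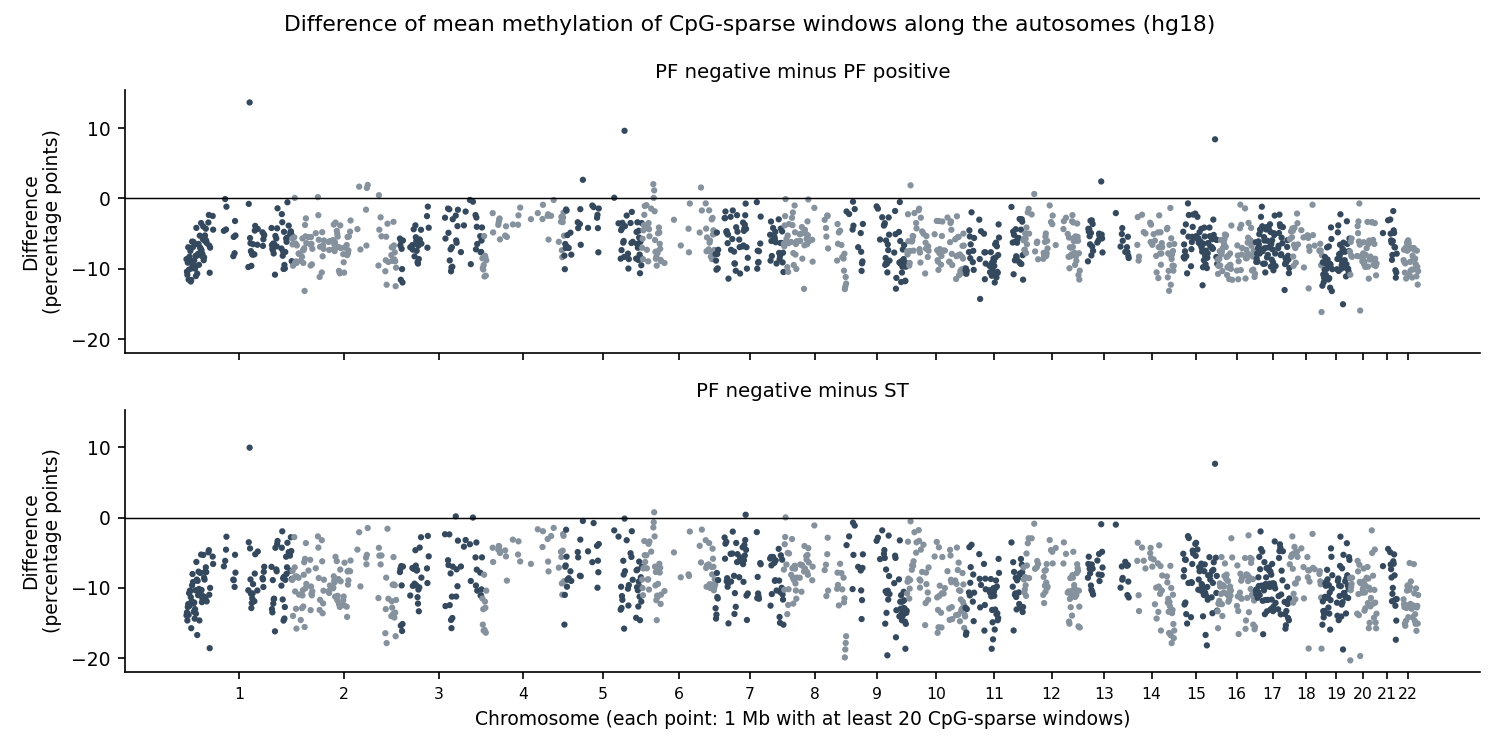
Difference of group means (percentage points) at CpG-sparse windows per megabase along the autosomes, 1 point per megabase. PF negative tumours lay below PF positive tumours in 1277 of 1295 megabases and below ST tumours in 1288.

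Whether PF negative tumours were above or below PF positive tumours differed with CpG surroundings even among windows of like level between 10% and 90% in ST tumours. This grouping was made after seeing the data. Under 10% in ST tumours, where 12834 of 14529 CpG-dense windows lay, CpG-dense windows differed by 0.222 points and CpG-sparse ones by −1.07. Neither passed its exact permutation test (adjusted p = 0.157 and 0.225). At 10% to 30% the differences were 7.16 and −6.57 points (both at adjusted p = 0.0152). Windows at 30% to 70% in ST tumours differed by −11.8 points if CpG-sparse (adjusted p = 0.0152 over 15 exact permutation tests). CpG-dense windows of that level were at 43.4% in PF negative and 27.8% in PF positive tumours, a difference of 15.6 points (SE 3.74, 451 windows, adjusted p = 0.0152 from the exact permutation test). At 70% to 90% in ST tumours the differences were −11.3 and 13.4 points, both at the same adjusted p. In windows at 90% or more in ST tumours the CpG-sparse difference was −4.43 points (adjusted p = 0.0379), and the CpG-dense one was −0.0577 points (SE 0.887).

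**Figure D5:**
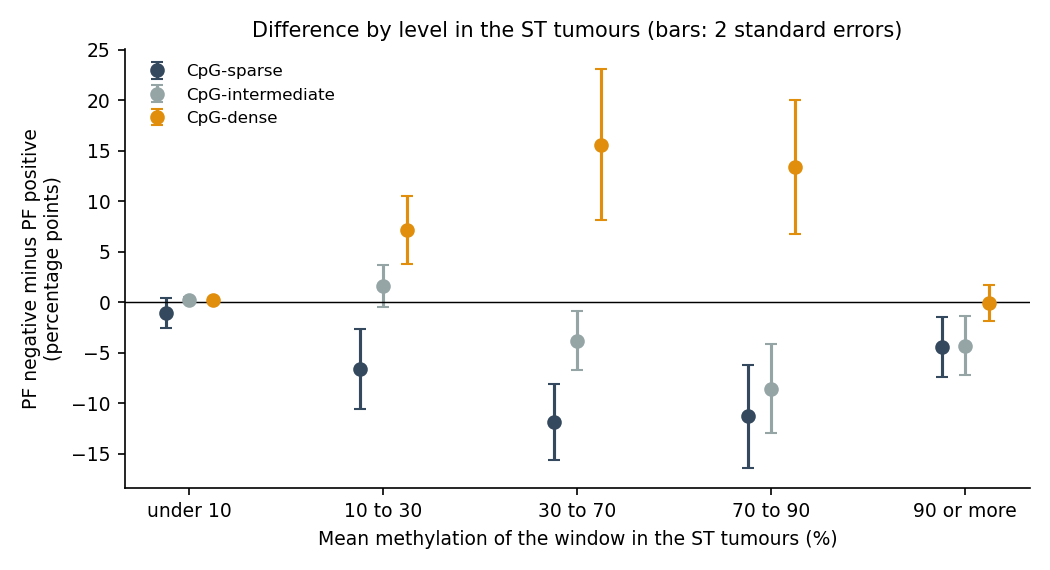
Difference of PF negative minus PF positive group means (percentage points, bars of 2 standard errors) for windows grouped by their mean methylation (percent) in ST tumours and by CpG surroundings. At 30% to 70% the CpG-sparse point lies at −11.8 and the CpG-dense point at 15.6.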

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

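Of the tests in this part, that of C-to-T variants was set before its result was seen, and those on conversion, loss of signal, other cells, labels and depth and the splits of the tumours were set down only after.

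Among 33 combinations of group and measure examined, 7 had a tumour standing far from the rest of its group, where chance gives about 1 in 20. ST 1 had the highest mean methylation of its group, 40.9% with the other ST tumours at 36.0% to 36.3%. It was also apart at CpG-sparse cytosines (83.3%, others 76.3% to 77.3%) and at CpG-intermediate cytosines (42.5%, others 36.1% to 36.8%). So it was in the share at 20% or less (54.3%, others 57.9% to 58.4%) and in the share at 80% or more (37.8%, others 31.1% to 32.0%). These 5 measures are of the same cytosines and are not independent. PF positive 4 had a median coverage of 33 reads, with 38 to 39 in the others of its group. PF positive 2 had 948 CpG-dense windows at 20% or more, with 741 to 773 in the others. Mitochondrial reads, which no comparison used, held C at a median of 0.12% of calls over the 16 tumours (0.0740% to 0.177%), above the limit of 0.00297% that a count of 0 allows, in 16 of 16 tumours. By group this share was 0.125% ± 0.0150 (SD, n = 8) in PF negative, 0.129% ± 0.0336 (SD, n = 4) in PF positive and 0.0823% ± 0.00903 (SD, n = 4) in ST tumours. It was lower in ST than in PF negative tumours (exact permutation p = 0.00202) and PF positive tumours (exact permutation p = 0.0286).

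The lower methylation of PF negative than PF positive tumours at CpG-sparse cytosines was weighed against 3 technical explanations. A loss of signal shared by all methylated cytosines needs a difference of −8.59 points in CpG-dense windows at 90% or more in ST tumours, and it was −0.0577 points (SE 0.887, 244 windows), which argues against it. A fall from C-to-T variants at single CpGs would vanish with the CpG that fell most. Without it the 3234 windows called lower had a median difference of −28.2 points (quartiles −38.4 to −20.6), against −32.9 with it. These windows were picked for a fall of at least 20 points, and 555 of them were CpG-intermediate and 3 CpG-dense. The values thus speak for these windows, and do not decide whether variants contribute to the mean difference. Other cells with low methylation at CpG-sparse cytosines cannot be told apart from a difference within the tumour cells, since composition was not measured. Even if unmethylated there, they would need a share of at least 9.51% for the mean difference. For the mean of the 3234 windows called lower they would need 47.0%. The named window on chromosome 18 from 46326001, at 92.1% in PF positive and 10.7% in PF negative tumours, would need a larger share. A difference between the tumour classes themselves stays open, untested, as a hypothesis.

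The higher methylation of PF negative than PF positive tumours at CpG-dense cytosines may be technical if bisulfite conversion was less complete. The share of C in mitochondrial reads differed by −0.00379 points (SE 0.0176) between the groups, where 1.19 points would be needed. This argues against a failure that mitochondrial DNA shared, but mitochondrial reads do not measure conversion in CpG-dense DNA. In the 12834 CpG-dense windows under 10% in ST tumours the difference was 0.222 points (SE 0.101), also short of 1.19 points. Other cells wholly methylated at these sites would need a share of at least 1.24% for the mean difference. For the mean of the 129 CpG-dense windows called higher they would need 55.3%. The named window on chromosome 4 from 48188001, at 8.65% in PF positive and 77.1% in PF negative tumours, would need a larger share. No measure of composition decides it. A difference between the classes stays open too. At CpG-dense cytosines ST tumours stood at 5.27%, near the 5.11% of PF negative and above the 3.92% of PF positive tumours. The comparison thus does not show a gain in PF negative rather than a loss in PF positive tumours. Unmethylated other cells in the PF positive tumours were not weighed.

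For ST 1, incomplete conversion that mitochondrial DNA shared would need 2.16 points more C in mitochondrial reads than in the other ST tumours. The difference was −0.00245 points. Deeper sequencing is argued against by its median coverage of 43 reads, within the 40 to 45 of the others. ST 1 lay 8.80 points from the other ST tumours, 10.6 from PF positive and 14.6 from PF negative tumours, so 1.77 points nearer its own group. A PF tumour under an ST label would not by itself give the excess, since ST 1 lay 5.16 points above the highest of the 12 PF tumours (35.7%), though its high mean is also what singled it out and its closest PF tumour (9.57) was nearer than its farthest ST tumour (9.64). No biological explanation was tested, since the labels give no division among ST tumours.

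Other splits of the tumours were run for each count of called windows. The 12 PF tumours allow 495 splits, of which 100 were run, the real one and others drawn at random. Of these 1, the real one, gave as many as its 3748 windows, and the highest of the others gave 319. Chance is thus unlikely to give this count, though a sample of the splits cannot exclude it. For PF negative against ST it was also 1 of 100 run out of 495, with 13782 windows and 42 as the highest other. For PF positive against ST, 2 of the 35 splits gave as many as the real 20 windows, the highest other giving 35, so chance cannot be excluded.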

How the results depend on the processing

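Of the alternatives given here, thinning to 10 reads, limma without the block on same-numbered tumours and the size-matched fits were chosen after seeing the data. The mean difference of PF negative from ST tumours, and their CpG-sparse difference (−10.6 to −8.29 points with 1 tumour left out), kept direction and call in every alternative with a test. Of 36 named windows, the 12 of PF negative against ST kept their call in every alternative, and of 662 results for single windows 501 kept it, 161 lost it and 0 reversed. Causes were not tested unless the alternative's construction shows them. With a minimum of 20 reads, which leaves 98545 windows, the mean difference of PF negative from PF positive was −1.82 (adjusted p = 0.0764). Called windows then numbered 2395 against PF positive, 8869 against ST and 12 for PF positive against ST, and 1388 were called in both. The share at 20% or less turned to −0.0847 there and to −0.0206 with each tumour's own cytosines. Own cytosines also gave mean differences of −2.52 (adjusted p = 0.0707) for PF negative minus PF positive and −3.41 (adjusted p = 0.138) for PF positive minus ST, and weighting by reads −3.14 (adjusted p = 0.113) for the latter, with the CpG-dense difference at −0.994 (adjusted p = 0.0800). Adjusted p ranged from 0.04 to 0.12 for the former and from 0.0429 to 0.188 for the latter over all alternatives. A threshold of 30 points gave 2430, 8713 and 1329 in both, and one of 10 points 32 for PF positive against ST. All 3 groups in the fit gave 233 for PF positive against ST. Cytosines on their own gave 8715, 49319 and 404 calls. Thinning gave 59 for PF positive against ST. The correlation distance of PF positive from ST was 0.0115 (one-sided exact p = 0.0571).

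limma on logit methylation called 7990 windows for PF negative against PF positive and 0 for PF positive against ST, with 11356 at an unadjusted p under 0.05 and 20 by the quasi-binomial model, and 5079 in both. Centred per tumour it called 6553 against ST, 0 for PF positive against ST (11222 unadjusted) and 1280 in both. Whether replicate numbers pair the tumours was not settled. Correlations of same-numbered deviations were low, from −0.121 to 0.138. The same number was the best match for PF negative 1, 3 and 4 and PF positive 1 and 2 against ST, and for PF negative 2 against PF positive. PF negative 2 and PF positive 3 and 4 against ST, and PF negative 1, 3 and 4 against PF positive, matched another number best. Over the same-numbered tumours, the replicate block gave mean differences of −1.32 (SE 0.551) for PF negative minus PF positive, −0.599 (SE 0.467) at CpG-intermediate cytosines and −0.632 (SE 0.625) for the share at 20% or less, which turned. With the replicate block, limma called 0 windows for PF negative against PF positive (23310 unadjusted), 5946 for PF negative against ST, 0 for PF positive against ST (11925 unadjusted) and 0 in both. On the same tumours without the block it called 93, 6566, 0 (11356 unadjusted) and 47 in both. Of the PF negative tumours this fit holds 1 to 4 only, so fewer than the main fit. Of the 12 windows named between PF negative and PF positive, 12 lost their call with the block and 6 on the same tumours without it.

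With 1 tumour left out in turn, called windows ranged from 691 (without PF positive 1) to 5822 (without PF positive 2) for PF negative against PF positive, 7201 (without ST 1) to 14819 for PF negative against ST. They ranged from 13 (without ST 4) to 47 (without PF positive 2) for PF positive against ST, and 443 (without PF positive 1) to 3336 in both. The mean difference ranged from −2.68 to −1.98 for PF negative minus PF positive and from −2.85 to −1.20 (without ST 1) for PF positive minus ST, and the distance of PF positive from ST from 0.266 (without ST 1) to 0.873. Directions turned for the share at 20% or less of PF negative minus PF positive (−0.209 without PF negative 7 to 0.400), the share between 20% and 80% of PF positive minus ST (−0.910 to 0.631) and the CpG-dense mean of PF negative minus ST (−0.424 to 0.381), none of which passed its test. Promoters and gene lists were not run, since no annotation of hg18 was used here. Thinning to 10 reads lowered the count from 3748 to 3035 windows for PF negative against PF positive and from 13782 to 11330 against ST. This does not show what more depth would add.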

Other observations

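All tests in this part were chosen only after the main results were seen.

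The number of CpG-dense windows at 20% methylation or more, out of 14529, was 1100.5 ± 136 (SD, n = 8) in PF negative, 807 ± 95.0 (SD, n = 4) in PF positive and 1125.25 ± 237 (SD, n = 4) in ST tumours. PF negative tumours had 293.5 more than PF positive tumours, with 7 of 8 above the PF positive range (exact permutation p = 0.00404, adjusted p = 0.0121). PF negative and ST tumours differed by −24.75 windows (exact permutation p = 0.842), and PF positive minus ST was −318.25 (exact permutation p = 0.0571, adjusted p = 0.0857).

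A hypothesis drawn from the data is that the fall at CpG-sparse windows may be larger in megabases with many tested windows. With windows placed in 4 bins by the number of tested windows in their megabase (1 to 43, 44 to 95, 96 to 197 and 198 to 632), PF negative minus PF positive was −4.46, −6.73, −8.03 and −9.72 points. Per tumour, the fullest minus the emptiest bin was −12.3 ± 2.43 (SD, n = 8) within PF negative, −7.03 ± 2.67 (SD, n = 4) within PF positive and −4.74 ± 2.94 (SD, n = 4) within ST tumours. It differed by −5.26 points (SE 1.59, exact permutation p = 0.0101) between PF negative and PF positive, with 6 of 8 below the PF positive range. Against ST tumours it differed by −7.55 points (exact permutation p = 0.00202), and PF positive minus ST by −2.29 points (exact permutation p = 0.371). Among windows at 90% or more in ST tumours, which start alike there, it was −3.43 points (SE 0.911, exact permutation p = 0.0182).

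A further hypothesis is that called windows may lie in runs. Of the windows called lower in PF negative than PF positive tumours, 24.0% had another within 10 kb, against a median of 7.79% and a highest of 9.86% in 100 random draws of as many tested windows. Of those called higher it was 25.9%, against 2.33% and 5.06%. Neighbouring windows need not be independent, so the draws do not separate runs set by biology from shared spread between tumours. The longest run called lower lay on chromosome 19 from 880001 to 911000, where 9 of 24 windows were called. Its mean was 45.1% ± 2.47 (SD, n = 8) in PF negative, 62.3% ± 2.20 (SD, n = 4) in PF positive and 68.6% ± 6.56 (SD, n = 4) in ST tumours. The longest called higher lay on chromosome 11 from 616001 to 631000, where 6 of 9 windows were called. The means there were 57.8% ± 8.38 (SD, n = 8), 31.7% ± 4.61 (SD, n = 4) and 30.2% ± 13.3 (SD, n = 4). Against ST tumours 52.2% of the windows called lower had another within 10 kb, with 28.2% as the highest of 100 draws. The longest run there lay on chromosome 16 from 999001 to 1141000, with 61 of 111 windows called.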
